A study of Arabidopsis thaliana with 6 samples.

How the data were processed

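Gene expression was measured in the root apex of wild-type Arabidopsis thaliana seedlings of the Columbia (Col-0) accession, grown on vertical plates of solid medium in continuous light and harvested at 8 days into RNAlater, a solution that stabilises RNA. Roots were cut into 2 pieces, per the labels' protocols. Zone I was the last 0.5 mm of the root, with the root cap and the division zone. Zone II was a section of 1.5 mm with the elongation zone and the root hair zone. There were 3 arrays of each zone, 6 in all. RNA was isolated with a PicoPure kit, amplified to cDNA with the Ovation Pico WTA system and labelled with biotin, per the labels' protocols.

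The authors deposited 1 table of signal intensity values for 22810 probe sets, which their processing notes credit to MAS5 and Affymetrix Expression Console. The versions, settings and array design are not given in the sources used here. The intensity values were on a linear scale and all above 0. On every array the mean after removal of the lowest and highest 2% of probe sets was 500, so each array had been scaled to the same trimmed mean before deposit. No detection calls were given with the values. The authors also deposited a table of their own comparison of the zones, with a log2 fold change, a p-value and an adjusted p-value per probe set. Neither the direction of that log2 fold change nor the test behind it is given in the sources used here. Its direction was taken as zone II over zone I, because it correlated positively with that difference in the signal table. The deposited adjusted p-values equalled a Benjamini-Hochberg adjustment of the deposited p-values.

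The normalization of the deposited intensities was kept, and log2 of the signal was taken with no offset. The 64 control probe sets were left out, which left 22746, with no filter on dim probe sets. Zone II was compared with zone I in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with an intensity trend, a two-sided moderated test, no block and Benjamini-Hochberg adjustment over all probe sets tested. A probe set was called at an adjusted p under 0.05. Differences are log2 of zone II minus zone I, so a positive value is higher in zone II, and they are given with their standard error (SE, 3 arrays per zone). Zone signals are geometric means of the 3 arrays. For a gene whose dimmer zone lay below 64, the difference after 64 was added to every signal stands beside the plain one, because the plain one is set by signals in the range of probe set noise.

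Probe sets were named by the locus identifiers in the authors' deposited table and by the gene symbols of the TAIR10.1 annotation. Of the probe sets tested, 22591 had a locus, 22091 of these were found in the annotation, and 21839 named 1 gene only. Each locus had 1 probe set. No genome build is given in the sources used here, so no coordinates are printed. Probe sets of the s_at or x_at kind, which can match near-identical transcripts, numbered 1061.

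Before the data were examined, 17 lists of root genes and 5 families defined by annotation text were fixed, together with the tests, the alternatives and the rule for the genes to name. The rule took, among probe sets that name 1 gene, the 6 largest differences in each direction among calls with no overlap between the zones' arrays and a signal above the median of all probe sets in the brighter zone. From each list it took the 3 called members with the largest difference and the called member furthest against the majority, or the largest difference where no member was called. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists, and again with camera at an estimated correlation and with fry. Fry tests whether the genes of a set move on balance one way, and it does not compare them with other genes. Counts of list members adjusted over the list alone are given beside the counts adjusted over all probe sets.

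The alternatives were the replicate number as a block, 16 or 64 added to the signals, quantile normalization, equal medians, a filter at the 40th percentile of mean signal, no intensity trend, robust eBayes, array weights, and each array left out in turn. Leaving out the first array of both zones together was added after seeing the data. The fit was tested on simulated data for the zone comparison, with 22746 probe sets at the real means and spread, of which 200 were changed. Of the simulated 2-fold changes 1% was recovered, of the 4-fold changes 21%, and of the 4-fold changes above the median signal 46.7%. In that simulation 1 of 23 calls was an unchanged probe set. The adjustment is less strict where more probe sets change, and the real comparison called 8623. These recovery rates therefore do not give the sensitivity of the real comparison. The number of arrays limits the precision, and depth in the sense of counts does not apply to them. Python 3.11.15 and matplotlib 3.10.9 drew the figures.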

Results

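The data compared 2 adjoining pieces of the Arabidopsis root apex: zone I, the last 0.5 mm with the root cap and dividing cells, and zone II, a 1.5 mm section with elongating cells and root hairs. Each zone was measured on 3 arrays. The labels do not say whether the 3 came from separate batches of seedlings, so the p-values measure the spread between these arrays, which may be technical. All arrays had been scaled to the same trimmed mean, and their median signals lay between 132.1 and 149.3. The share of probe sets with a signal under 64 was 35.2% to 39.6% per array. The series title names a comparison of the apex by microarray and RNA-seq, of which the array part is analysed here.

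Between the zones, 8623 of 22746 probe sets (37.9%) differed at an adjusted p under 0.05 (limma). Of these, 4114 were higher in zone II and 4509 were higher in zone I. At least 2-fold differences were found for 7394 of them, 3611 higher in zone II and 3783 higher in zone I. The 3 arrays of one zone did not overlap the 3 of the other for 11339 probe sets (49.9%), where chance gives 10%. Differences of at least 8-fold were more frequent in zone II, with 1403 against 625. Their total of 2028 dropped to 600 when 64 was added to every signal. Among all 8623 calls, of any size, the dimmer zone had a mean signal under 64 in 2301.

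Among the genes with the largest differences toward zone I was AN3 (AT5G28640), a transcriptional coactivator that promotes cell proliferation. Its signal was 1987 in zone I and 2.62 in zone II, a log2 difference of -9.57 ± 0.55 (SE, n = 3 per zone) with an adjusted p of 1.67e-06, or -4.94 with 64 added. The others were ATLP-1 (AT1G18250) at -8.42, the GATA-type zinc finger gene GATA4 (AT3G60530) at -7.99, AT3G15240, annotated as an unknown protein, at -7.95, the Ole e 1 and extensin family gene AT5G10130 at -7.69, and AT2G16230 at -7.58. With 64 added these 5 lay at -4.37, -4.04, -5.82, -5.36 and -2.98, so that AT3G15240 and AT5G10130 then differed more than AN3. Toward zone II the largest difference was that of CASP1 (AT2G36100), a membrane protein of the Casparian strip, the lignin barrier of the endodermis. Its signal was 18391 in zone II and 4.66 in zone I, a log2 difference of 11.95 ± 0.64 (SE) with an adjusted p of 1.21e-06, or 8.02 with 64 added. Also among the largest were the peroxidase gene AT5G66390 (10.76), the pectinesterase gene AT5G04960 (10.54), the root hair expansin EXPA18 (10.49) and the extensin-like gene AT4G08400 (10.46). With 64 added these 4 lay at 7.48, 7.69, 6.76 and 5.46. The probe set of AT4G08400 is of the s_at kind and may also read related extensin genes, so its gene is uncertain.

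Genes of mitosis and cytokinesis were higher in zone I in 18 of 20 measured members and in none higher in zone II. Adjusted over the list alone, 19 were higher in zone I, and without the intensity trend 11 were. The list median was -3.53 (-1.99 with 64 added, camera adjusted p = 2.05e-06, and adjusted p = 0.235 with an estimated correlation). The syntaxin KN, which builds the cell plate in dividing cells, had a signal of 2136 in zone I and 28.9 in zone II (-6.21 ± 1.24, SE, adjusted p = 0.00224; -4.05 with 64 added). CDC20.2, an activator of the anaphase-promoting complex, lay at -6.93 (-3.56 with 64 added), on an s_at probe set that may also read its near-identical neighbour. The B-type cyclin CYCB2;4 lay at -5.29 (-1.96 with 64 added), and its adjusted p was 0.0541 without the intensity trend. All 20 members were higher on zone II array 1 than on the mean of zone II arrays 2 and 3, by a median of 2.12 on the log2 scale. Without that array the list median was -4.42.

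DNA replication genes were higher in zone I in 16 of 20 members, also when adjusted over the list alone, with a median of -1.20 (-0.999 with 64 added, camera adjusted p = 4.45e-06, and adjusted p = 0.145 with an estimated correlation). The replication licensing factor CDT1A had a signal of 755.3 in zone I and 91.0 in zone II (-3.05 ± 0.36, SE, adjusted p = 7.07e-05). The ribonucleotide reductase subunit TSO2 lay at -2.88, and the replication fork factor CDC45 at -5.09 (-1.52 with 64 added). Core histone genes were higher in zone I in 14 of 21 members, 15 when adjusted over the list alone (median -2.58, or -1.35 with 64 added; camera adjusted p = 9.49e-05, and adjusted p = 0.197 with an estimated correlation). The histone H3 genes AT5G10400 and AT3G27360 lay at -4.08 and -3.97, and the H2B gene AT5G02570 at -4.00 (-1.40 with 64 added). Kinesins went both ways, with 20 of 47 higher in zone I and 8 higher in zone II (21 and 8 when adjusted over the list alone), and the family as a whole did not pass (median -0.69, or -0.49 with 64 added, camera adjusted p = 0.0858). It passed at 0.0393 when the first array of both zones was left out, and at 0.0182 with fry. POK2, a kinesin that orients the phragmoplast of dividing cells, lay at -5.03 (-2.32 with 64 added). The kinesins AT4G24170 and AT1G18410 lay at 5.22 and 4.87 (1.46 and 2.34 with 64 added). AT4G24170 lost its call when the first array of both zones was left out (4.09, adjusted p = 0.0586).

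Ribosome and ribosome biogenesis genes were higher in zone I in all 19 measured members, also when adjusted over the list alone (median -1.89, or -1.78 with 64 added, camera adjusted p = 2.38e-09, and adjusted p = 0.145 with an estimated correlation). NUC-L1, a nucleolin that acts in ribosomal RNA production, had a signal of 15254 in zone I and 2659 in zone II (-2.52 ± 0.21, SE, adjusted p = 7.84e-06). NOP56, a protein of the nucleolar particles that methylate ribosomal RNA, lay at -2.72 and the pumilio protein APUM24 at -2.58. Among cytosolic ribosomal proteins picked by annotation, 172 of 202 were higher in zone I and 1 was higher in zone II (173 and 2 when adjusted over the list alone), with a median of -1.62 (-1.58 with 64 added, camera adjusted p = 3.42e-27, and adjusted p = 0.123 with an estimated correlation). Of these, 8 belong to one of the named lists too. The S11 gene AT4G30800 had a signal of 3430 in zone I and 238.0 in zone II (-3.85 ± 0.24, SE, adjusted p = 2.39e-06). AT3G48960 and AT5G40040 lay at -3.94 and -3.47, from signals of 51.7 and 45.2 in zone I, and at -0.80 and -0.70 with 64 added. AT5G40040 lost its call without zone I array 2 or 3 (-3.54 and -2.90) and without zone II array 1 or 3 (-2.94 and -3.07), and without the first array of both zones (-3.44). The member higher in zone II was RPL18AA, with a difference of 1.79.

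Stem cell niche and meristem regulators were higher in zone I in 6 of 15 members, also when adjusted over the list alone, and in none higher in zone II (median -0.84, or -0.61 with 64 added, camera adjusted p = 0.0167, and adjusted p = 0.160 with an estimated correlation). The call ended when probe sets below the 40th percentile of mean signal were left out (adjusted p = 0.260), which left 3 of 10 members higher in zone I. The 3 largest differences were those of the PLETHORA transcription factors, which set root stem cell identity. PLT1 lay at -5.55 ± 0.87 (SE, adjusted p = 0.000456), PLT2 at -5.08 and PLT3 at -4.32, with -2.28, -1.91 and -2.52 after 64 was added. Genes of epidermal patterning, which set hair and non-hair cell fates, were higher in zone I in 7 of 10 members, 8 when adjusted over the list alone (median -2.04, or -1.47 with 64 added, camera adjusted p = 0.00155, and adjusted p = 0.119 with an estimated correlation). The MYB factor WER had a signal of 4988 in zone I and 127.2 in zone II (-5.29 ± 0.69, SE, adjusted p = 0.000139). Its bHLH partner EGL3 lay at -5.24 and the receptor-like kinase gene SUB at -4.67 (-2.74 and -2.07 with 64 added). On zone II array 1, where the mitosis genes were highest, WER had its lowest signal of the 3 arrays, 30.9 against 159.7 and 416.8.

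The root cap list was divided. Of 17 members, 8 were higher in zone I and 4 were higher in zone II (9 and 4 when adjusted over the list alone), and the list as a whole did not pass (median -2.19, or -1.12 with 64 added, camera adjusted p = 0.180). Without zone II array 3 the median was -1.38. Without the intensity trend, and also without zone I array 2, 5 members were higher in zone I. It passed at 0.0364 when the first array of both zones was left out, and at 0.0442 with fry. The cap identity factors SMB and FEZ lay at -4.83 ± 1.24 and -4.43 ± 1.28 (SE, adjusted p = 0.00955 and 0.0179), and at -1.96 and -1.12 with 64 added. Without the intensity trend their adjusted p-values were 0.0581 and 0.0534, and FEZ also lost its call without zone I array 2 (-4.27) or 3 (-4.02) and without the first array of both zones (-4.14). The members higher in zone II were DMP4 (5.46, or 2.89 with 64 added), RNS3 (4.12), BFN1 (2.68, or 1.83 with 64 added) and PASPA3 (2.08). DMP4 followed the naming rule and the other 3 were named after their values were seen. All 4 are known as markers of developmental cell death, and RNS3, BFN1 and PASPA3 are also known from maturing xylem. The 8 members higher in zone I were all lower on zone I array 1 than on the mean of zone I arrays 2 and 3, by a median of -0.95.

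**Figure D1:**
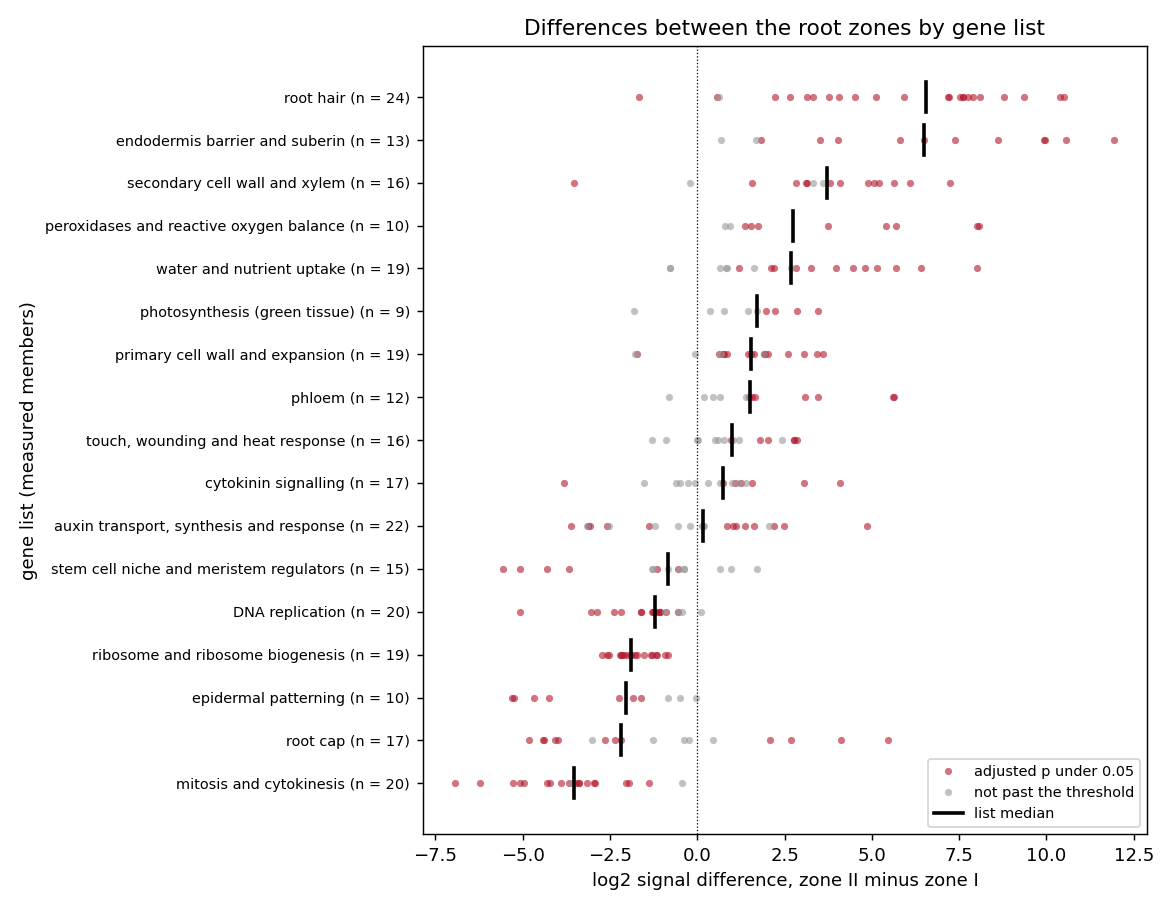
Log2 signal difference between the zones (x axis, zone II minus zone I) for each measured member of the 17 named gene lists (y axis, number of members in brackets). Red points are members with an adjusted p under 0.05, grey points are the others and black bars are list medians, which run from -3.53 for mitosis and cytokinesis to 6.55 for root hair genes.

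Root hair genes were higher in zone II in 22 of 24 members, 23 when adjusted over the list alone (median 6.55, or 4.55 with 64 added, camera adjusted p = 1.34e-12, and adjusted p = 0.0476 with an estimated correlation). The root hair peroxidase RHS19 had a signal of 16163 in zone II and 12.1 in zone I (10.38 ± 0.94, SE, adjusted p = 1.34e-05; 7.49 with 64 added). EXPA18 lay at 10.49 and the proline-rich wall protein PRP3 at 9.35 (6.76 and 6.78 with 64 added). The exception was RHD6, the transcription factor that starts hair formation, which was higher in zone I (-1.68 ± 0.37, SE, adjusted p = 0.00422). Arabinogalactan and extensin proteins were higher in zone II in 42 of 77 members and higher in zone I in 3 (44 and 3 when adjusted over the list alone), with a median of 1.77 (0.93 with 64 added; camera adjusted p = 1.62e-08, and adjusted p = 0.0892 with an estimated correlation). Besides AT4G08400, the extensin genes EXT13 and EXT6 lay at 9.28 and 7.84 (6.58 and 6.15 with 64 added), the second on an x_at probe set that may also read related genes. The largest difference toward zone I in this family was that of AT5G10130, given above. Without the first array of both zones 5 members were higher in zone I. Of this family, 4 members belong to a named list too.

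Genes of the primary cell wall and expansion were higher in zone II in 14 of 19 members, 15 when adjusted over the list alone, and 1 was higher in zone I (median 1.54, or 1.41 with 64 added, camera adjusted p = 6.27e-05, and adjusted p = 0.173 with an estimated correlation). The xyloglucan endotransglucosylases XTH17, XTH18 and XTH21, which cut and rejoin wall xyloglucan, lay at 3.59 ± 0.36, 3.42 ± 0.27 and 3.06 ± 0.39 (SE, adjusted p = 2.59e-05, 6.10e-06 and 0.000112). The expansin EXPA1 was higher in zone I (-1.74, adjusted p = 0.0147). Its call ended without the intensity trend (adjusted p = 0.0750), without zone I array 1 (-1.52, adjusted p = 0.0721) and without the first array of both zones (-1.01).

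The endodermis barrier list was higher in zone II in 11 of 13 members, also when adjusted over the list alone (median 6.48, or 4.31 with 64 added; camera adjusted p = 3.11e-08, and adjusted p = 0.0476 with an estimated correlation). Besides CASP1, CASP2 had a signal of 8481 in zone II and 8.56 in zone I (9.95 ± 0.75, SE, adjusted p = 5.46e-06; 6.77 with 64 added). The suberin genes CYP86A1 and GPAT5, named after their values were seen, were the 2 members that did not pass. Their signals in zone II were 27.7 and 13.2, with adjusted p-values of 0.338 and 0.653. Secondary wall and xylem genes were higher in zone II in 12 of 16 members, 14 when adjusted over the list alone (median 3.71, or 2.23 with 64 added; camera adjusted p = 1.70e-05, and adjusted p = 0.0476 with an estimated correlation). The lignin laccases LAC4 and LAC17 lay at 7.24 ± 0.89 and 6.08 ± 0.82 and the xylem protease XCP1 at 5.63 ± 0.97 (SE, adjusted p = 8.93e-05, 0.000161 and 0.000856; 3.64, 3.00 and 4.12 with 64 added). ACL5, a thermospermine synthase that delays xylem cell death, was higher in zone I (-3.53, or -1.69 with 64 added). It lost its call without zone I array 2 (-3.33, adjusted p = 0.0512). Phloem genes were higher in zone II in 7 of 12 members, also when adjusted over the list alone (median 1.52, or 1.02 with 64 added, camera adjusted p = 0.00474, and adjusted p = 0.145 with an estimated correlation). Without zone II array 2 the count was 4 of 12. The phloem lectin PP2-A1 lay at 5.62 ± 0.92 and the sieve element protein SEOR1 at 5.60 ± 0.51 (SE, adjusted p = 0.000602 and 1.42e-05; 3.01 and 3.42 with 64 added). The sucrose transporter SUC2 of companion cells lay at 3.46, at 1.77 with 64 added and at 2.26 without zone I array 3, and its adjusted p was 0.0580 without the intensity trend.

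Water and nutrient uptake genes were higher in zone II in 12 of 19 members, 14 when adjusted over the list alone, and none was higher in zone I (median 2.70, or 2.08 with 64 added, camera adjusted p = 4.45e-06, and adjusted p = 0.119 with an estimated correlation). The tonoplast aquaporin TIP2;2 had a signal of 8375 in zone II and 32.6 in zone I (8.00 ± 0.51, SE, adjusted p = 2.78e-06; 6.42 with 64 added). TIP2;3 lay at 6.40 and the copper transporter COPT2 at 5.68 (3.41 and 3.16 with 64 added). On zone I array 1 the list was higher than on the mean of zone I arrays 2 and 3 by a median of 0.71, and without that array the list median was 2.70. Peroxidases and regulators of reactive oxygen were higher in zone II in 8 of 10 members, also when adjusted over the list alone (median 2.73, or 2.30 with 64 added, camera adjusted p = 8.25e-05, and adjusted p = 0.183 with an estimated correlation). PER7 and PER44 lay at 8.06 ± 0.73 and 8.00 ± 0.40 (SE, adjusted p = 1.33e-05 and 9.58e-07; 5.75 and 6.06 with 64 added). PER34 lay at 5.69 (2.88 with 64 added) on an s_at probe set that may also read a near-identical copy. Among class III peroxidases picked by annotation, 27 of 57 were higher in zone II and 1 was higher in zone I, also when adjusted over the list alone (median 1.76, or 0.85 with 64 added; camera adjusted p = 1.02e-05, and adjusted p = 0.0476 with an estimated correlation). With 64 added, and also without the intensity trend, 3 were higher in zone I. Of the 57, 10 are in a named list too. PER64, which acts at the Casparian strip, lay at 9.93 (7.05 with 64 added), and the member higher in zone I was AT2G43480 at -4.13 ± 0.38 (SE, adjusted p = 1.45e-05).

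Auxin genes went both ways. Of 22 members, 8 were higher in zone II and 5 were higher in zone I, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.607). The number higher in zone I was 3 without zone I array 2 or 3 and without the intensity trend, and 8 against 7 higher in zone II without zone II array 3. Its median was 0.16 (0.14 with 64 added) and its mean -0.16. The auxin exporter PIN2 had a signal of 2190 in zone I and 249.5 in zone II (-3.13 ± 0.51, SE, adjusted p = 0.000581), and the Aux/IAA gene IAA30 lay at -3.62 (-1.17 with 64 added). TAR2, an enzyme of auxin synthesis, was higher in zone II (4.87 ± 1.02, SE, adjusted p = 0.00305; 2.33 with 64 added). Cytokinin signalling genes were higher in zone II in 6 of 17 members and higher in zone I in 1 (8 and 1 when adjusted over the list alone). Without the intensity trend the counts were 3 and 0, and without zone I array 2 they were 4 and 0. The list median was 0.73 (0.59 with 64 added, camera adjusted p = 0.0304, and adjusted p = 0.202 with an estimated correlation). The list's call ended without zone I array 3 (median 0.80, adjusted p = 0.0597), without zone II array 1 (0.74, adjusted p = 0.113) and without the first array of both zones (0.81, adjusted p = 0.0929). The cytokinin receptor AHK3 had a signal of 1515 in zone II and 182.1 in zone I (3.06 ± 0.41, SE, adjusted p = 0.000151), and the biosynthesis gene IPT5 lay at 4.08 (1.45 with 64 added). The response regulator ARR15 was higher in zone I (-3.81, adjusted p = 0.0212; -1.33 with 64 added). Its adjusted p was 0.0526, 0.0853 and 0.0602 without zone I array 1, 2 and 3 (-4.02, -3.58 and -3.84), and 0.0675 without the intensity trend. Without zone II array 3 its difference was -2.38.

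Lists for other tissue and for handling were also measured. Photosynthesis genes of green tissue were higher in zone II in 4 of 9 members, also when adjusted over the list alone (median 1.72, or 0.91 with 64 added; camera adjusted p = 0.0209, and adjusted p = 0.358 with an estimated correlation). Without zone II array 1 the median was 1.08 (adjusted p = 0.0475). The photosystem I subunit PSAD1 had a signal of 1202 in zone II and 109.5 in zone I (3.46 ± 0.43, SE, adjusted p = 9.78e-05). The photosystem II protein PSBO1 lay at 2.85 and the Rubisco activase RCA at 2.24. Genes of the touch, wounding and heat response were higher in zone II in 6 of 16 members, also when adjusted over the list alone (median 1.00, or 0.49 with 64 added; camera adjusted p = 0.00851, and adjusted p = 0.119 with an estimated correlation). Without the first array of both zones 4 were higher in zone II. The zinc finger gene ZAT12 lay at 2.78 ± 0.34, the calmodulin-like gene TCH3 at 2.77 ± 0.53 and ERF4 at 2.86 ± 0.67 (SE, adjusted p = 8.77e-05, 0.00175 and 0.00566), with ERF4 at 1.73 after 64 was added. ERF4 lost its call when the first array of both zones was left out (1.96, adjusted p = 0.0742).

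Across all lists, 19 of 22 were called at the preset correlation. With an estimated correlation 4 were called: root hair, secondary cell wall and xylem, endodermis barrier, and class III peroxidases.

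**Figure D2:**
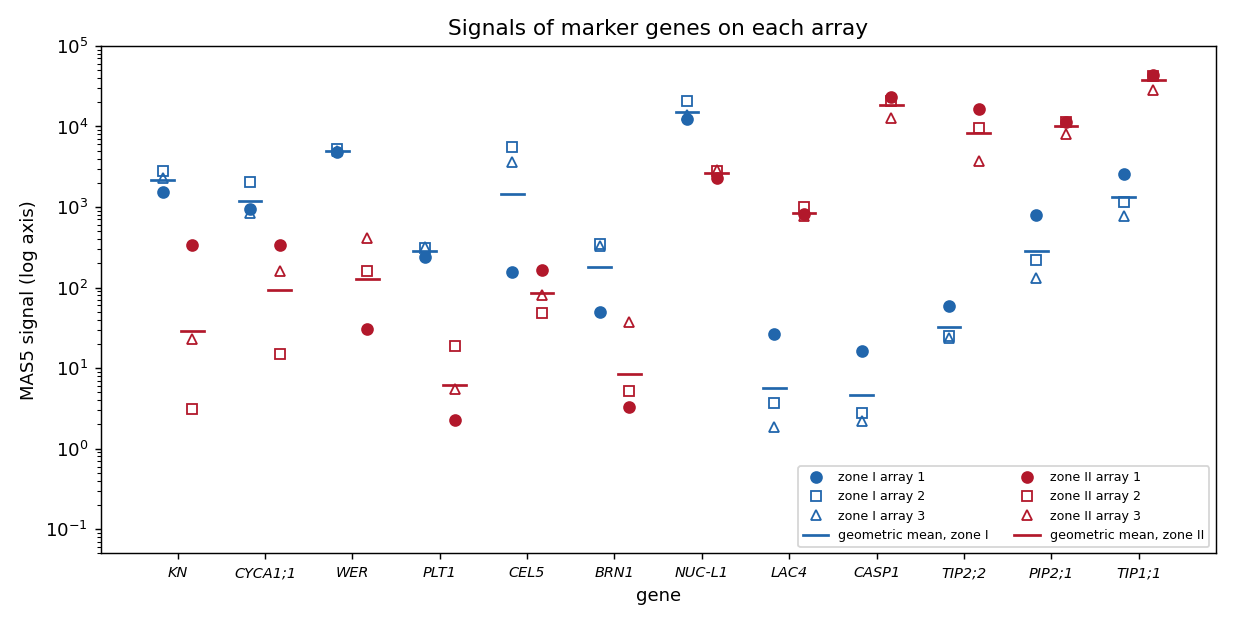
MAS5 signal on a log axis (y axis) of 12 genes (x axis) on each of the 3 zone I arrays (blue) and the 3 zone II arrays (red), with horizontal lines at the geometric mean of each zone. The genes shown were picked after their values were seen. The mitosis gene KN was at 337.8 on zone II array 1 and at 3.10 and 23.0 on zone II arrays 2 and 3, and the cap gene CEL5 was at 154.7 on zone I array 1 and at 5545 and 3643 on zone I arrays 2 and 3.

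The arrays separated by zone. Across probe sets, which are not independent replicates, the correlation of log2 signals was 0.875 to 0.904 within a zone and 0.717 to 0.778 between zones, and the first principal component held 56.2% of the variance. Zone I array 1 correlated with the zone II arrays at 0.757 to 0.778, and zone I arrays 2 and 3 at 0.717 to 0.742. No pair of arrays held identical values in over 1% of probe sets. The 3' to 5' signal ratio of control transcripts, a measure of RNA integrity, was 1.17 ± 0.08 in zone I and 1.11 ± 0.07 in zone II for GAPDH and 6.08 ± 0.75 and 7.37 ± 1.68 for actin (SD, n = 3). For ubiquitin it was 5.08 ± 0.17 and 5.12 ± 0.14. The exact two-sided permutation p was 0.4 for GAPDH, 0.3 for actin and 0.8 for ubiquitin, where 3 against 3 cannot go below 0.1. Actin's ratio was highest on zone II array 1, at 8.92 against 7.62 and 5.58 on zone II arrays 2 and 3. The GAPDH ratio there was 1.11 against 1.17 and 1.04, and the ubiquitin ratio 4.98 against 5.25 and 5.14. The residual SD of log2 signals was 1.59 in the dimmest 10% of probe sets and 0.31 in the brightest. Quantile normalization moved the median of all differences from -0.04 to -0.15 and equal medians moved it to -0.12, and under both the named genes kept their direction and call.

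The authors' deposited table was set against the recomputed differences. At an adjusted p under 0.05, the authors' deposited table held 10370 calls, 4542 of them positive and 5828 negative, and 6900 were at least 2-fold. Of the calls in the authors' deposited table, 8106 were also called in the recomputed test, all with the same sign, 2264 were not, and 517 recomputed calls were missing from it. Of the shared calls, 3815 were higher in zone II and 4291 higher in zone I. The log2 differences correlated with those of the authors' deposited table at r = 0.870 (Spearman rho = 0.871) across probe sets. The slope of the differences of the authors' deposited table on the recomputed ones was 0.60, from 0.05 in the dimmest 10% of probe sets to 0.96 in the brightest. For CASP1 the log2 fold change in the authors' deposited table was 8.53, and for AN3 it was -5.71.

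**Figure D3:**
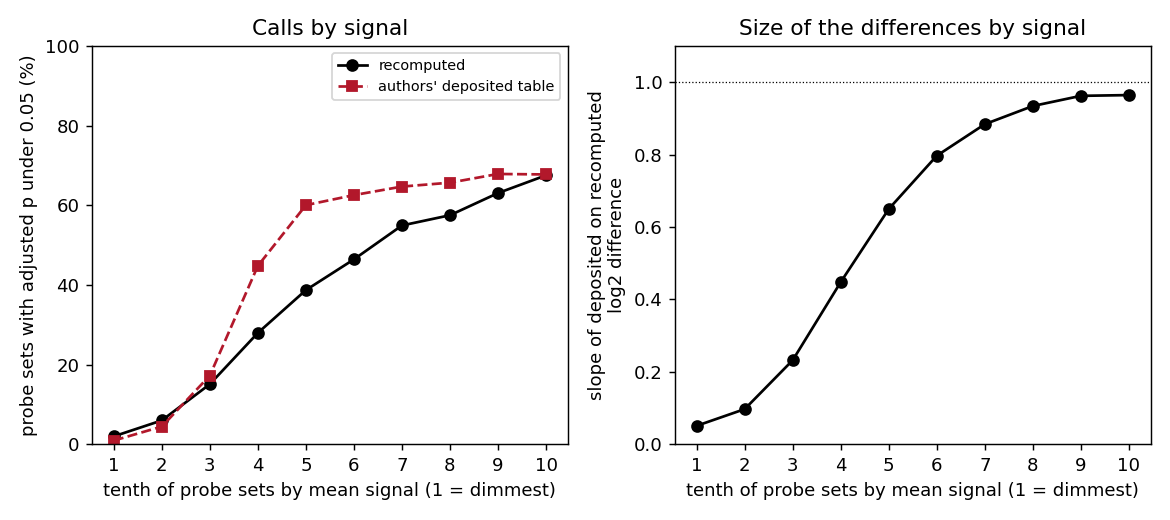
Left, share of probe sets with an adjusted p under 0.05 (y axis, percent) in 10 bins of mean signal (x axis) in the recomputed test (black) and in the authors' deposited table (red), which reached 67.5% and 67.7% in the brightest bin. Right, slope of the authors' deposited log2 differences on the recomputed ones (y axis) in 10 bins of mean signal, which went from 0.05 to 0.96.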

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

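The alternatives left the counts of calls within 1.5 times of 8623 and all named genes that were tested in their direction. The count ran from 7095 to 8293 when each array was left out in turn, and was 7081 without the intensity trend, 9159 with 64 added and 7189 without the first array of both zones, a setting chosen after seeing the data. Of the 77 named genes, 71 kept their call without the trend, 72 without the first array of both zones, and 73 to 77 without any single array. The filter at the 40th percentile left 52 of the 77 to test, and these 52 kept their call. The count of differences of at least 8-fold was 1155 with 16 added, 600 with 64 added and 1155 after the filter at the 40th percentile, because offsets shrink differences from dim signals and the filter removes dim probe sets. The same settings moved the mean correlation within a zone from 0.891 to 0.947, 0.965 and 0.924. They moved the correlation with the authors' deposited table from 0.870 to 0.955, 0.978 and 0.974. That correlation was 0.844 to 0.860 without any single array and 0.836 without the first array of both zones, where fewer arrays were used. The 19 lists called at the preset correlation numbered 4 with an estimated one. In the touch, wounding and heat, secondary wall and class III peroxidase lists the estimate was under the preset 0.01 (-0.0107, -0.0205 and -0.00298). Their camera adjusted p still rose, from 0.00851 to 0.119, from 1.70e-05 to 0.0476 and from 1.02e-05 to 0.0476. A higher correlation was thus not the cause in these lists, and no other cause was tested. The loss of calls with an estimated correlation can therefore not be read as an effect of the correlation alone. With fry, 21 lists were called. The median of the list auxin transport, synthesis and response, which was not called, was 0.16 with all arrays and ran from -0.0512 (without zone II array 3) to 0.36 (without zone II array 1). Its adjusted p was 0.968 without zone II array 3 against 0.607 with all arrays, and the cause was not tested. The replicate number as a block gave 8445 calls. The deviations of same-numbered arrays from their zone means correlated at 0.004, 0.036 and 0.037, all under 0.1, so the numbers were not taken to pair the arrays. A filter on detection calls was not run, since the values came without calls, and averaging the probe sets of a gene moves nothing here, as each locus had 1. Signal over background limits the dim probe sets, with 1.98% called in the dimmest 10% and 67.5% in the brightest.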

Other observations

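The families, genes and tests below were chosen after the data were seen, except the splits of the arrays. Families were picked by annotation text, 26 in all, besides tubulins, whose text pattern matched no probe set and was dropped. None passed with an estimated correlation. Chaperonins were higher in zone I in 16 of 17 members (median -1.86, or -1.82 with 64 added; camera adjusted p = 2.49e-08, and adjusted p = 0.0628 with an estimated correlation), RNA helicases in 38 of 58 (median -1.14, or -0.92 with 64 added; 8.52e-09, and adjusted p = 0.0769 with an estimated correlation) and aminoacyl-tRNA synthetases in 35 of 54 (median -1.26, or -1.12 with 64 added; 3.58e-08, and adjusted p = 0.0738 with an estimated correlation). Pentatricopeptide repeat proteins, which process RNA in mitochondria and plastids, were higher in zone I in 111 of 327 members and higher in zone II in 3 (median -1.39, or -0.65 with 64 added; 6.10e-12, and adjusted p = 0.0628 with an estimated correlation). Mitochondrion-encoded genes were higher in zone I in 31 of 49 members (median -1.11, or -0.96 with 64 added; 4.20e-07, and adjusted p = 0.193 with an estimated correlation). Chloroplast-encoded genes were higher in zone I in 27 of 79 members and higher in zone II in 1 (median -0.44, or -0.42 with 64 added, camera adjusted p = 0.000625, and adjusted p = 0.465 with an estimated correlation). The growth-regulating factors GRF1 and GRF3, known as partners of AN3, lay at -5.51 ± 0.70 and -5.14 ± 0.47 (SE, adjusted p = 0.000111 and 1.40e-05; -3.56 and -3.53 with 64 added). The GRF family as a whole did not pass (3 of 6 higher in zone I, camera adjusted p = 0.163).

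In zone II, WRKY transcription factors were higher in 26 of 60 members and 1 was higher in zone I (median 1.35, or 0.66 with 64 added; camera adjusted p = 1.26e-06, and adjusted p = 0.0628 with an estimated correlation). WRKY31 and WRKY75 lay at 5.05 ± 1.00 and 4.99 ± 0.81 (SE, adjusted p = 0.00222 and 0.000592), from zone I signals of 4.65 and 4.73, and at 1.63 and 1.64 with 64 added. WRKY61, WRKY25 and WRKY47 lay at 4.27, 4.19 and 3.43, and with 64 added they differed more, at 1.99, 2.56 and 2.11. Glutathione transferases were higher in zone II in 21 of 51 members (median 0.99, or 0.71 with 64 added; camera adjusted p = 0.000352, and adjusted p = 0.168 with an estimated correlation), and the one higher in zone I, ATGSTF13, lay at -7.45 (-3.80 with 64 added). Leucine-rich repeat receptor kinases were higher in zone II in 53 of 133 members and higher in zone I in 16 (median 0.90, or 0.53 with 64 added; camera adjusted p = 0.000246, and adjusted p = 0.0628 with an estimated correlation). Terpene synthases went both ways, with 6 of 28 higher in zone II and 3 higher in zone I, and the family did not pass (camera adjusted p = 0.422). Its members AT1G33750 and AT1G31950 lay at -7.32 and -5.81 (-4.10 and -4.52 with 64 added).

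The split of the 6 arrays by zone gave 8623 calls, and the highest of the other 9 splits gave 0. With 10 splits no share can be under 0.05, and 1 split, the one by zone, gave as many calls. Each of the other 9 splits put arrays of both zones in both groups, so the zone difference widened the spread within them. Their 0 calls therefore do not show what a grouping of like arrays would give.

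Mitosis genes were higher on zone II array 1 than on the mean of zone II arrays 2 and 3 in all 20 members, with a median deviation of 2.12 on the log2 scale. This was picked from 22 lists on 6 arrays, so it was set against random lists matched on mean signal with an adjustment over all 132 medians. The adjusted p was 0.0264, the lowest that 10000 random lists allow. The matching used the mean over all 6 arrays, while the mitosis genes were mostly dimmer in zone II. On zone II arrays 2 and 3 KN was at 3.10 and 23.0, and AUR1 at 291.1 and 220.9. Dim probe sets vary more, so the random lists can be too narrow and noise at low signal stays open. Of the 132 medians, 14 passed 0.05 in this way. Among them was the mitosis list on zone I array 2, which deviated by 0.66 (adjusted p = 0.0264). On zone I array 1 the mitosis list deviated by -0.56 and did not pass (adjusted p = 0.211). The list thus varied between arrays in zone I too. On zone II array 1 the core histones deviated by -0.82 and the DNA replication genes by 0.27. Whether tissue of the composition of whole zone I lay in that section is not settled. A count of genes went against it, and the medians below decide nothing. The mitosis genes would need a share of 16.6% of such tissue (bootstrap interval 8.35 to 25.6). At the lower bound of that share, 164 other abundant zone I genes would need a level of at least 64 on this array. Members of the mitosis, replication, histone and kinesin lists were left out, but other division genes stayed in. CYCA2;4 was at 155.4 against a needed 68.7, and CYCA2;3 at 25.2 against 79.1. Of the 164 genes, 36 fell 4-fold or more short of their level, 18 fell 10-fold or more short, and 73 reached it. The noise of matched probe sets gave at most 17 and 11 in 10000 draws. Those draws took each gene independently, while lists such as the core histones shifted as a whole on this array. That range can therefore be too narrow. Among the genes that fell short, AN3 was at 3.38 against a needed 166.3, AT5G10130 at 4.18 against 308.1, and WER at 30.9 against 416.9. Among the 73 that reached their level, PCK1 was at 1134 against a needed 202.6 and HB-2 at 167.9 against 72.2. The median over 220 such genes alone decides nothing, at 0.514 of the level at the full share (0.326 to 1.08 with the share resampled too). Members of the stem cell niche and epidermal patterning lists, at 0.708 (0.176 to 2.96, with 6 of 15 at 1 or more), decide nothing either. The count of genes that fell short was added after these medians had been seen. An earlier median test held the share fixed and argued against such tissue, and a first one had used zone II array 1 to pick the genes.

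Dividing cells of lateral root primordia stay open as a source. The 14 lateral root markers, written down after the pattern had been seen but before this test was run, had a median deviation at percentile 51.8 of random lists, which decides nothing. PUCHI was at 221.4 on zone II array 1 against 3.81 and 6.04 on arrays 2 and 3, and DOT5 at 75.1 against 4.73 and 11.1. TMO7 was at 2.80 against 134.8 and 747.0, and IAA28, the brightest in zone II, at 3999 against 4286 and 4609. Over all arrays 6 markers were higher in zone II, among them LBD16 (5.80, or 2.57 with 64 added) and GATA23 (5.31, or 2.79 with 64 added). The 2 markers higher in zone I were TMO7 (-6.61, or -4.87 with 64 added) and GLV6 (-2.98, or -1.80 with 64 added). Of the markers 1 is also in the auxin list. Tissue from the upper end of the division zone alone was not tested and stays open. A difference in RNA quality or amplification on zone II array 1 was not tested either.

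On zone I array 1 the root cap list was lower than on zone I arrays 2 and 3 by a median of -0.66 and the uptake list was higher by a median of 0.71. Other lists higher on that array were the peroxidases and reactive oxygen balance (1.23) and root hair (0.65) lists, both with an adjusted p of 0.0264 over the 132 medians. The photosynthesis list (0.85) did not pass, with an adjusted p of 0.158. On zone I array 3 the peroxidase and root hair lists deviated the other way, by -0.97 and -0.33, both with an adjusted p of 0.0264. Zone I array 2 lay at -0.01 and 0.08, so these lists were spread over all 3 zone I arrays. Cytosolic ribosomal proteins were lower on zone I array 1, by -0.13 (adjusted p = 0.0264 over the 132 medians). Noise stays open for the cap genes, with an adjusted p of 0.581 over the 132 medians. It stays open for the uptake genes too, with an adjusted p of 0.0264 and 12 of 19 members higher on that array. The random lists were matched on the mean over all arrays, while uptake, root hair and peroxidase genes were mostly dimmer in zone I. Dim probe sets vary more, so the random lists can be too narrow for all of these lists. A uniformly lower share of cap tissue stays open, since 2 tests of it disagreed. The deviations of the 8 cap genes higher in zone I spread beyond the average noise at their signals (chi-square p = 6.77e-31), with CEL5 at -4.86 and ARF16 at -0.01, but their SD lay at percentile 91.1 of matched random lists. The SD test was added after the chi-square result had been seen, and the chi-square alone would have argued against a uniform share. Zone II tissue in the section stays open too. The uptake genes would need a share of 2.31%, with a bootstrap interval of -1.56 to 7.91 that includes 0, and 33 root hair and endodermis genes reached a median of 0.417 of the level this would bring. Both sets of genes were picked by their calls over all 6 arrays, zone I array 1 included. That favours genes that were low on this array, so the 0.417 can be too low.

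The log2 differences in the authors' deposited table were smaller than the recomputed ones for dim probe sets. An origin in noise and in the handling of low signals is consistent with the slopes. With 64 added to the signals the slope of the deposited on the recomputed differences was 1.08 over all probe sets, and without it the slope was 0.96 in the brightest 10% and 0.05 in the dimmest. The summary method behind the authors' deposited table is not given in the sources used here and was not tested, and no biological explanation was tested.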
